A study of Mus musculus with 16 samples.

How the data were processed

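Total RNA from whole testes of B6xCBA mice aged 3 months was measured on 16 Illumina mouse bead arrays, which read biotinylated cRNA with probes attached to beads. The 16 arrays formed 4 groups of 4: mice with a testis-specific Musashi-1 transgene (TgMsi1), their wild-type littermates (Wt(TgMsi1)), mice with a testis-specific Musashi-2 transgene (TgMsi2), and the wild-type littermates of those (Wt(TgMsi2)). Group and replicate number were taken from the sample titles. The labels do not say that the 4 replicates of a group are separate mice, so p-values measure only the spread between these samples, which may be technical. Bead arrays give no read depth, and the number of arrays limits the precision.

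The deposited value table holds log2 values of 25697 probes on all 16 arrays. GenomeStudio was named in the submitters' processing notes, with no version. The normalization of the deposited log2 values is not given in the sources used here, but the sorted columns of the 16 arrays differed by at most 0.006, which quantile normalization over all arrays produces. The deposited log2 values ran from 7.37 to 14.51, and the median was 7.83 on each array. No value lay near 0, so a background level may have been left in or an offset added. Fold changes of dim probes may therefore be understated. The authors also deposited a comparison table for each transgene, with an unadjusted p-value per probe, the ratio of transgenic to wild type and a signed fold change (a score that gives the negative reciprocal of ratios under 1), per the file headers. The test and the selection behind the authors' p-values and ratios are not given in the sources used here. All 246 probes of the TgMsi1 table had a fold of at least 1.2 and a p-value of at most 0.0499, and all 700 probes of the TgMsi2 table had a fold of at least 1.5 and a p-value of at most 0.0488. The TgMsi1 table holds 246 of the 499 probes with a fold over 1.2 and an unadjusted p under 0.05 in limma, and the TgMsi2 table holds 700 of the 706 past 1.5 and 0.05, so counts of list members in the TgMsi1 table miss genes that may have changed. The log2 of each ratio in the authors' tables differed from the difference of group means in the value table by at most 5.9e-06, so both describe the same values.

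A further table of unnormalized values has 128 per-array columns that no label ties to a sample, and these were not used in any step. The planned background correction, the planned filter on detection p-values and the slide as a block need those columns. The test was therefore run on the deposited log2 values of all 25697 probes, with no filter, which departs from the plan. Only the gene symbol and probe number of that table (2 columns) were used, to count which genes the array design holds.

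Gene names were available for the 932 probes of the deposited comparison tables only, which cover 840 genes. Of these probes, 849 matched a RefSeq gene of GRCm38.p6 through their Entrez number, and 144 symbols were updated from it. Chromosome positions are those of the probes in the deposited tables. Their genome build, and whether a probe lies in coding or untranslated sequence, are not given in the sources used here. The array design holds 1 probe for Msi1 and 2 for Msi2, but 0 of these are in the deposited comparison tables, so the transgenes' own transcripts could not be read and the genotype labels were not checked by them.

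Each transgenic group was compared with its own wild-type littermates in limma 3.58.1 under R 4.3.3 (lmFit with 1 mean per group over all 16 arrays, contrasts, eBayes). The difference between the 2 transgene effects was tested as an interaction contrast of the same fit. Adjusted p-values are Benjamini-Hochberg values over 25697 probes, with a threshold of 0.05, and fold changes are differences of log2 means with the standard error (SE) of the fit. On simulated data, with 25697 probes drawn from the spread of these arrays and changes placed in probes with a mean log2 above 8, the fit recovered 58 of 100 probes given a log2 change of 0.5 and 97 of 100 given a change of 1 in the TgMsi1 comparison, where 7 of 162 calls were false. In the simulated TgMsi2 comparison it recovered 63 and 95 of 100, and 14 of 172 calls were false. The simulated noise was drawn separately for each probe and array, without shifts shared by many probes of an array. The share of false calls on the real arrays may therefore be higher.

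The gene lists, the rule for named genes, the comparisons and most alternatives were set before the data were examined. For each transgene the rule took the 10 rises and 10 falls with the largest log2 change among probes past the threshold whose 4 transgenic arrays all lay to 1 side of the 4 wild-type arrays, which has an exact probability of 0.0286 in 8 unrelated arrays. It counted 1 probe per gene and left out predicted genes and clones. Up to 4 members of each list with the smallest adjusted p were added, and where fewer than 5 probes passed in a direction, the 5 with the smallest p were given as values. The 26 lists hold 563 genes, of which 488 are on the array. They are markers of spermatogonia, late spermatocytes, round and elongating spermatids, Sertoli, Leydig, peritubular myoid, endothelial and immune cells, epididymis and blood, and genes of the meiotic axis, the piRNA pathway, reported Musashi targets, germ cell mRNA storage and translation control, splicing, p53 targets, mitotic cell cycle, DNA replication, sperm axoneme, immediate early and heat shock response, unfolded protein response, Notch, cytosolic ribosome, cholesterol synthesis and oxidative phosphorylation.

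The planned list tests (camera and fry) and an adjustment over each list alone need names for all probes, and the named probes had been selected on these same samples. They were replaced, after the data were seen, by Fisher's exact test of how many of a list's genes stand in a deposited comparison table, against 16936 named genes of the array design. The test was one-sided, ran over 52 list and direction pairs per comparison and was adjusted by Benjamini-Hochberg. Genes of a list are correlated, so these p-values are too small. The 16936 genes were not limited to those with bright probes, which may also make these p-values too small. The direction of a list's members within the TgMsi2 table was tested with a 2-sided Fisher's exact test. Scores per array are the mean of a set's higher probes minus the mean of its lower probes, and score and marker differences were tested with exact permutation tests (2-sided) over the 70 relabelings of 8 arrays. Alternatives were array weights, an intensity trend with robust variance, the replicate number as a block, each comparison from its own 8 arrays, other thresholds, and each array left out in turn. A filter at a mean log2 of 8 (10831 probes) and fits without named pairs of arrays were added after seeing the data. Lists, scores and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.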

Results

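Musashi-1 and Musashi-2 are RNA-binding proteins that regulate the translation, splicing and stability of target transcripts. The arrays compared whole adult testes of mice that overexpress 1 of the 2 proteins from a testis-specific transgene with testes of wild-type littermates, separately for Musashi-1 (TgMsi1 against Wt(TgMsi1)) and Musashi-2 (TgMsi2 against Wt(TgMsi2)), with 4 arrays per group. Whole testis holds germ cells of all stages together with Sertoli, Leydig, peritubular myoid, endothelial and immune cells. Values are normalized log2 signals. Arrays of the same group correlated across probes with r between 0.988 and 0.996, and 0 pairs of arrays were identical. The first principal component held 43.6% of the variance. The TgMsi2 arrays lay at 34.7, 13.2, 29.6 and 8.9 on it (replicates 1 to 4), TgMsi1 replicate 2 lay at 10.5, and every other array lay below 0, between -16.0 and -3.5. Msi1 and Msi2 themselves stand in neither deposited comparison table, so their levels are not reported here.

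In TgMsi1 testes, few transcripts differed from wild-type littermates by more than the spread between arrays. Ppa2, which encodes the mitochondrial inorganic pyrophosphatase, rose by 0.49 on the log2 scale (SE 0.07), a 1.41-fold change, from 10.58 ± 0.15 to 11.07 ± 0.04 (SD, n = 4 each; adjusted p = 0.0444 in limma). Ano10, a member of the anoctamin family of membrane proteins, fell by 0.42 (SE 0.06), from 9.31 ± 0.08 to 8.89 ± 0.10 (SD, n = 4 each; limma adjusted p = 0.0483). The predicted transcript LOC100045782 fell by 0.68 (SE 0.09, limma adjusted p = 0.0444). The rule for named genes leaves out predicted genes, so this transcript was added after its result was seen. The 2 other named Ppa2 probes had TgMsi1 log2 differences of 0.40 and 0.48 that did not pass (limma adjusted p 0.139 and 0.385). In each of the 3 called transcripts, all 4 transgenic arrays lay to 1 side of all 4 wild-type arrays. The Ppa2 probe lies on chromosome 3 (133002232 to 133002281) and the Ano10 probe on chromosome 9 (122085284 to 122085333).

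Further transcripts with small p-values in TgMsi1 testes missed the threshold, with adjusted p-values in limma of 0.0632 to 0.139. Among those with higher values were Ott (log2 difference 0.74), an X-linked testis-expressed gene, the transcription factor Spdef (0.56), Fez1 (0.52), Ambp (0.43) and the cytochrome oxidase assembly factor Cox20 (0.30). Among those with lower values were Cnst (-0.63), the interferon-responsive Epsti1 (-0.60), Gdpd1 (-0.46), the Fanconi anaemia gene Fancd2 (-0.42) and Slc45a4 (-0.31). Prm3, a protamine-family gene of late spermatids, had a log2 difference of -0.85 (SE 0.25) with an adjusted p of 0.354.

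None of the 26 lists passed in TgMsi1 testes. The authors' deposited TgMsi1 table holds 246 of the 499 probes with a fold over 1.2 and an unadjusted p under 0.05 in limma, so a gene's absence from it does not show that the gene did not change. Of the germ cell lists, late spermatocyte markers had 1 of 17 members on the array in the authors' deposited table (Ccna1, -0.34) and elongating spermatid markers had 1 of 22 (Gapdhs, -0.31), while spermatogonia (20), meiotic axis (22) and round spermatid (21) markers had 0. Of the somatic and contaminating cell types, macrophage and immune markers had 1 of 16 (Fcer1g, 0.53), and Sertoli (19), Leydig (20), myoid (10), endothelial (10), epididymis (8) and blood (5) markers had 0. Single members also came from the reported Musashi targets (Tbx1, 0.79), p53 targets (Tnfrsf10b, 0.58), mitotic cell cycle (Cdc20, 0.32), the sperm axoneme (Spag16, 0.34) and oxidative phosphorylation (1 of 29, lower). Germ cell mRNA storage and translation control had Ybx3 (0.36) and Pabpc2 (-0.44). The piRNA, splicing, DNA replication, immediate early and heat shock, unfolded protein response, Notch, ribosomal and cholesterol lists had 0. The lowest adjusted p of Fisher's exact test was 0.871, against shares of 0.67% (higher) and 0.68% (lower) among all named array genes, and 0 list members passed limma's threshold over all probes.

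Of 25697 probes, 3 passed in the TgMsi1 comparison (1 higher, 2 lower), and 1881 had an unadjusted p under 0.05 in limma. These calls were not stable. With 1 array left out, limma called 30 probes without Wt(TgMsi1) replicate 2, 5 without TgMsi2 replicate 1 or 4, 3 without Wt(TgMsi2) replicate 4, and 1 without TgMsi1 replicate 1 or 4 or Wt(TgMsi1) replicate 3. It called 0, with 1576 to 1979 probes at an unadjusted p under 0.05, without TgMsi1 replicate 2 or 3, Wt(TgMsi1) replicate 1 or 4, TgMsi2 replicate 2 or 3, or Wt(TgMsi2) replicate 1, 2 or 3. Ano10 then stayed past the threshold only without Wt(TgMsi1) replicate 2 or TgMsi2 replicate 1 or 4, and Ppa2 only without these or Wt(TgMsi2) replicate 4. Elsewhere the limma adjusted p reached 0.227 for both genes (without Wt(TgMsi1) replicate 4). From the 8 arrays of the line alone, limma called 0 probes, with 1791 at an unadjusted p under 0.05. Ppa2 and Ano10 also lost their calls with an intensity trend and robust variance. In that fit 5 of 47 named genes that had missed the threshold passed. Ano10 lost its call with the replicate number as a block too.

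In TgMsi2 testes, at least 5 of 19 Sertoli, 4 of 20 Leydig and 4 of 16 immune cell markers rose against wild-type littermates. At least 2 of 21 round spermatid markers fell. Of all 25697 probes, limma called 1594 higher and 1366 lower. In a fit of the 10831 probes with a mean log2 above 8, it called 1733 higher and 1577 lower. These calls need no fold, whereas the marker counts cover only genes of the deposited TgMsi2 table, all with a fold of at least 1.5. With a fold over 1.5 added, limma called 374 of the 25697 probes higher and 261 lower. Those probes include dim ones, whose fold changes may be understated. The marker counts alone are therefore not ranked against the shares of probes called. Timp1, an inhibitor of matrix metalloproteinases, rose most among the named genes, by 2.18 on the log2 scale (SE 0.33) or 4.52-fold, from 8.05 ± 0.14 to 10.22 ± 0.79 (SD, n = 4 each; limma adjusted p = 0.00193). The secreted glycoprotein Lrg1 (log2 change 2.03, SE 0.42) and Robo4, a receptor of vascular endothelium (2.01, SE 0.26), each rose about 4-fold. Adipoq, the fat cell hormone adiponectin, fell by 1.87 (SE 0.32), from 10.74 ± 0.29 to 8.87 ± 0.22 (SD, n = 4 each; limma adjusted p = 0.00409). The spermatid gene Prm3 fell by 1.45 (SE 0.25), from 12.54 ± 0.09 to 11.09 ± 0.16 (SD, n = 4 each; limma adjusted p = 0.00404). The Timp1 probe lies on chromosome X (20451675 to 20451724), the Robo4 probe on chromosome 9 (37221433 to 37221482) and the Adipoq probe on chromosome 16 (23157666 to 23157715).

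Of the 10 largest rises taken by the rule, 9 are named here. After Timp1, Lrg1 and Robo4 these were the cofactor Lbh (log2 change 1.72), the siderophore-binding lipocalin Lcn2 (1.66), the kallikrein Klk1b27 (1.48), the serine protease inhibitor Serpina3g (1.41), the TWEAK receptor Tnfrsf12a (1.40) and the transglutaminase Tgm2 (1.38), with limma adjusted p from 0.000573 to 0.0277. Lcn2 was already bright in wild type (12.59 ± 0.44) and reached 14.26 ± 0.06 (SD, n = 4 each). Klk1b27 and Serpina3g belong to families of near-identical genes whose transcripts a probe can share, and their identity is uncertain. Other large falls were the IgM receptor Fcmr (-1.78), Adam21 (-1.59) and Adam30 (-1.32), members of a family of membrane proteases with testis-expressed genes, the neuronal adhesion molecule Ntm (-1.45), the vesicle coat protein Sec23a (-1.44), the olfactory receptor Olfr303 (-1.37), the cytochrome P450 Cyp2a12 (-1.34) and the secretory pathway pseudokinase Fam20a (-1.32), with limma adjusted p from 0.000251 to 0.0251. In each of these genes all 4 transgenic arrays lay beyond all 4 wild-type arrays, as the rule for naming them required. Leaving out 1 array ended the call of 3 of them. Klk1b27 lost it without TgMsi2 replicate 1 or 3 or Wt(TgMsi2) replicate 1 or 3 (limma adjusted p 0.0658 to 0.0868), Serpina3g without TgMsi2 replicate 1 or Wt(TgMsi2) replicate 2, 3 or 4 (0.0503 to 0.0643), and Cyp2a12 without TgMsi2 replicate 1 or 3 or Wt(TgMsi2) replicate 4 (0.0654 to 0.0798).

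**Figure D1:**
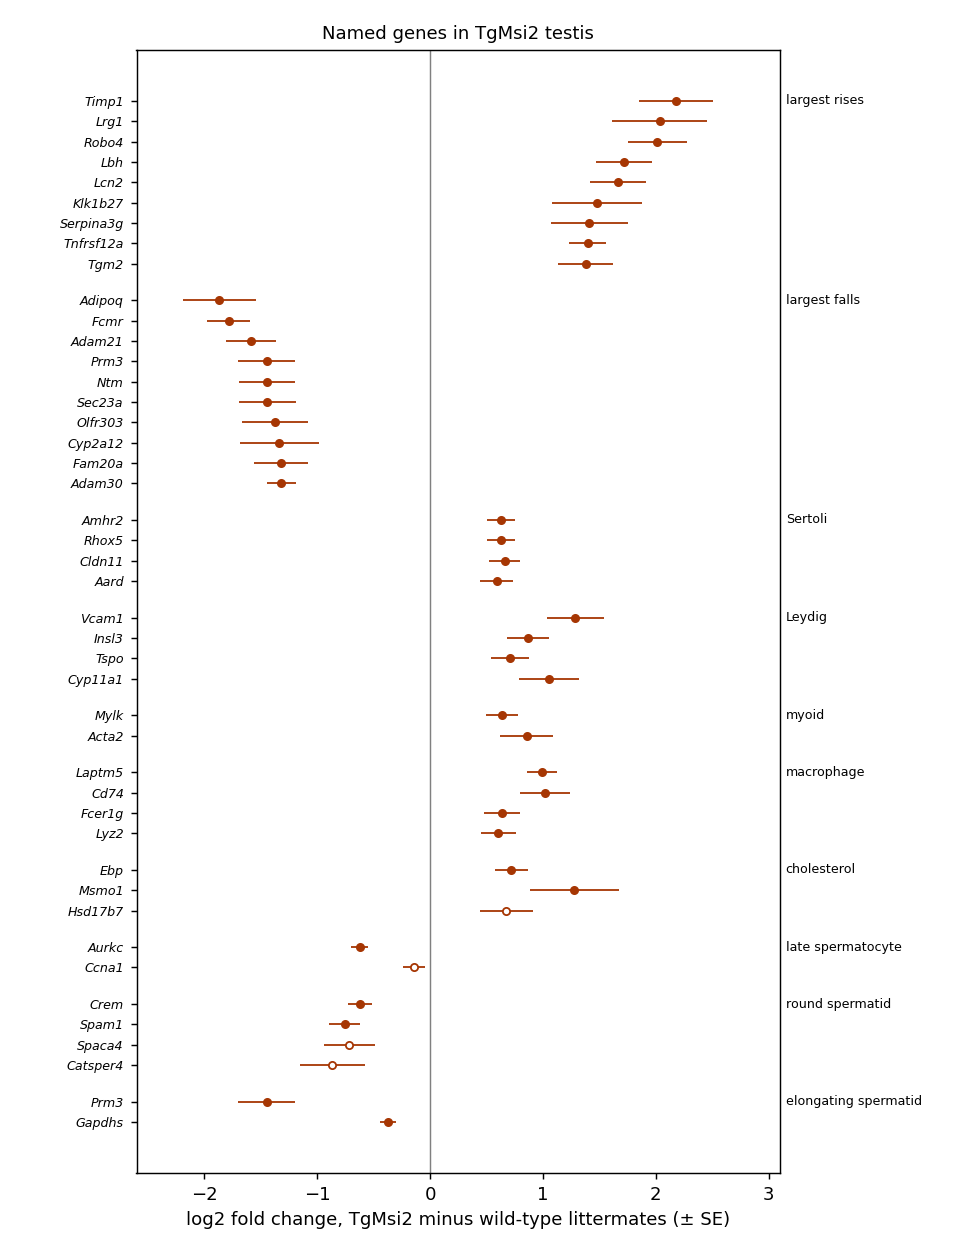
Log2 fold change of named genes in TgMsi2 testes against wild-type littermates (horizontal axis; points are limma estimates from 4 arrays per group, bars are standard errors), with filled points for adjusted p under 0.05 and open points otherwise. Rises reach 2.18 (Timp1) and falls -1.87 (Adipoq). The Sertoli, Leydig, myoid and macrophage members shown all lie above 0, and the spermatocyte and spermatid members shown all lie below 0. Only members selected into a deposited table are shown, at most 4 per list, and most members of each list are not.

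Markers of somatic cell types were over-represented among the genes listed as higher in the authors' deposited TgMsi2 table. Of 19 Sertoli cell markers on the array, 6 were in the table, all higher, and 5 passed limma's threshold (Fisher's exact test, adjusted p = 7.73e-05), among them the claudin Cldn11 (0.66), the homeobox gene Rhox5 (0.63), the anti-Müllerian hormone receptor Amhr2 (0.62) and Aard (0.59). Of 20 Leydig cell and steroidogenesis genes, 6 were in the table, all higher, and 4 passed (Fisher's exact test, adjusted p = 7.73e-05): the adhesion molecule Vcam1 (1.29), the cholesterol side-chain cleavage enzyme Cyp11a1 (1.05), the Leydig hormone Insl3 (0.87) and the mitochondrial translocator protein Tspo (0.71). Of 16 macrophage and immune markers, 4 were in the table and all rose (Fisher's exact test, adjusted p = 0.00417): Cd74 (1.02), Laptm5 (0.99), Fcer1g (0.64) and Lyz2 (0.61). Among 10 peritubular myoid markers the smooth muscle actin gene Acta2 (0.86) and Mylk (0.64) rose, but the list did not pass (adjusted p = 0.163). Endothelial (10), epididymis (8) and blood (5) markers had 0 members in the table. Probes outside the 2 deposited tables have no name in these data, so members that passed with a smaller fold cannot be counted, and the numbers that passed are minimums. For comparison, 2.17% of named array genes were listed as higher and 1.52% as lower. These shares include genes of dim probes. The list tests were not repeated among brighter genes, so their p-values may be too small. Since the table was selected on these samples, the direction of its members is not independent evidence, and within the table no list's direction passed (Fisher's exact test, adjusted p 0.075 to 0.272 over 5 lists).

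Of the germ cell lists, round spermatid markers passed the list test against all named array genes, with falls. Of 21 round spermatid markers, 4 were in the table, all lower (Fisher's exact test, adjusted p = 0.00417). Of these, Crem, a transcription factor of spermiogenesis, fell by 0.62 (SE 0.11) and the sperm hyaluronidase Spam1 fell by 0.76 (SE 0.14). Catsper4, a sperm calcium channel subunit (-0.86), and Spaca4 (-0.72) missed limma's threshold (adjusted p 0.0662 and 0.0543), and both passed, which made 4 members, without TgMsi1 replicate 2 or TgMsi2 replicate 4. Of all 8 named genes that missed it in TgMsi2, 3 passed with array weights and 3 over probes with a mean log2 above 8. Late spermatocyte markers had 1 of 17 (the meiotic kinase Aurkc, which fell by 0.62) and elongating spermatid markers 1 of 22 (Prm3), with an adjusted p of 1 for both lists. Gapdhs, the sperm glyceraldehyde phosphate dehydrogenase, also fell by 0.37 (SE 0.07, limma adjusted p = 0.00618), and its probe is not in the deposited TgMsi2 table. Spermatogonia (20) and meiotic axis (22) markers had 0 members in the table. The mean of the 4 round spermatid genes was lower by 0.74 in TgMsi2 than in wild type (value -0.74), while the means of the Sertoli, Leydig, myoid and macrophage members were higher by 0.68, 0.91, 0.75 and 0.81. These genes were selected for a change in the same arrays, so no p-value is given for these means. The same means differed in TgMsi1, where the genes had not been selected, by -0.26, 0.09, 0.25, 0.00 and 0.05 (exact permutation p 0.2, 0.486, 0.0571, 0.971 and 0.629).

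Of the pathway lists, cholesterol synthesis had 3 of 17 members higher in the deposited TgMsi2 table (Fisher's exact test, adjusted p = 0.0569, not passing). Ebp rose by 0.72 and the sterol oxidase Msmo1 by 1.28, with limma adjusted p of 0.00872 and 0.0488, and Hsd17b7 had a value of 0.67 that missed the threshold (adjusted p = 0.0798). With 1 array left out, Msmo1 stayed past it only without TgMsi1 replicate 2, TgMsi2 replicate 2 or Wt(TgMsi2) replicate 4, and otherwise its limma adjusted p was 0.0515 to 0.144. Msmo1 also lost its call with an intensity trend and robust variance, with the replicate number as a block, and from the line's own arrays alone. Other lists had 1 or 2 members in the table and adjusted p-values of 1. The members that rose were the transcription factor Tbx1 (0.81) of the reported Musashi targets, Tnfrsf10b (0.75) of the p53 targets, the small heat shock protein Hspb1 (0.95), the unfolded protein response factor Xbp1 (0.67), the X-linked ribosomal protein genes Rps4x (0.90) and Rpl39 (0.83), and Ndufa4 (0.69) of oxidative phosphorylation. Pabpc2, a testis-expressed poly(A)-binding protein gene of the translation control list, fell by 0.65. Tbx1 was placed in the list from work on Musashi-2 in mouse testis that may have used these samples, so its rise is not independent evidence. Piwil1, also in that list, is in neither deposited table and has no value here. The piRNA, splicing, mitotic cell cycle, DNA replication, axoneme and Notch lists had 0 members in the table.

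In all, 2960 of 25697 probes passed in the TgMsi2 comparison, 1594 higher and 1366 lower, and 6286 had an unadjusted p under 0.05 in limma. The balance turned in the fit of the line's own 8 arrays, with 1015 higher and 1254 lower. Of the called probes 703 carry a name, for 633 genes. All 700 probes of the authors' deposited TgMsi2 table had the table's direction in limma, and 635 of them passed. TgMsi2 replicates 1 and 3 lay furthest from wild type, and the count rested partly on them: limma called 1305 probes without TgMsi2 replicate 1, 1433 without TgMsi2 replicate 3, and 201 without both, a fit added after seeing the data. That last fit keeps only 2 transgenic arrays, and no other pair of TgMsi2 arrays was left out, so lost power was not separated from these arrays. Limma called 1799 without Wt(TgMsi2) replicate 3 and 1781 without Wt(TgMsi2) replicate 4. Of 48 named genes that passed, 0 changed sign in any setting, 13 lost their call when some single array was left out, and 34 lost it without both TgMsi2 replicates 1 and 3. Among list members, without TgMsi2 replicate 1 or 3 the Sertoli members that passed numbered 3 and the Leydig members 2, and without Wt(TgMsi2) replicate 3 the Sertoli members numbered 3. Without both TgMsi2 replicates 1 and 3, 0 Sertoli, Leydig, round spermatid and cholesterol synthesis members passed in limma, and 2 macrophage members did, with 3443 probes at an unadjusted p under 0.05. Aard lost its call without these 3 arrays (limma adjusted p 0.0568 to 0.0695), Acta2, Cyp11a1 and Tspo without TgMsi2 replicate 1 or 3 (0.0567 to 0.0939), and Ndufa4 and Rpl39 without either of these or Wt(TgMsi2) replicate 2 or 3 (0.0576 to 0.108), Ndufa4 also without Wt(TgMsi2) replicate 4 (0.0534). Lyz2 lost it without TgMsi2 replicate 1 or Wt(TgMsi2) replicate 2 or 4 (0.0536 to 0.0823), Fcer1g without TgMsi2 replicate 3 or Wt(TgMsi2) replicate 1 (0.0519 to 0.0684), and Tbx1 without Wt(TgMsi2) replicate 1 or 3 (0.0518 and 0.057).

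The direct test of whether the 2 transgene effects differ called 1 named gene. Tm9sf2, a membrane protein of the endosomal pathway, had a log2 change of -0.61 in TgMsi2 and 0.03 in TgMsi1, a difference of -0.64 (SE 0.08, limma adjusted p = 0.0426). Its level was 8.21 ± 0.09 in TgMsi2, 8.81 ± 0.06 in Wt(TgMsi2), 8.78 ± 0.06 in TgMsi1 and 8.75 ± 0.12 in Wt(TgMsi1) (SD, n = 4 each). The unnamed probe ILMN_1377919 changed by 0.49 in TgMsi2 and 0.05 in TgMsi1, a difference of 0.44 (SE 0.06, limma adjusted p = 0.0426), at a mean signal of 7.93 near the array median. Apart from these 2 probes, a call in TgMsi2 testes with no call in TgMsi1 testes was not shown to differ between the transgenes, and 2821 probes had an unadjusted p under 0.05 for the difference. With 1 array left out, limma called 107 probes without TgMsi1 replicate 2, 10 without TgMsi2 replicate 4, 8 without Wt(TgMsi1) replicate 3, 6 without TgMsi2 replicate 2, 5 without Wt(TgMsi1) replicate 4, and 1 without Wt(TgMsi1) replicate 1 or TgMsi2 replicate 3. It called 0, with 2262 to 2624 probes at an unadjusted p under 0.05, without TgMsi1 replicate 1 or 4 or Wt(TgMsi2) replicate 2, 3 or 4. Tm9sf2 lost its call in these last 5 fits and without TgMsi2 replicate 3 (limma adjusted p 0.0606 to 0.155). With the replicate number as a block, Tm9sf2 and ILMN_1377919 both lost their calls.

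Several genes moved the same way with both transgenes. All 3 transcripts called in TgMsi1 were also called in TgMsi2: Ppa2 rose by 0.51, Ano10 fell by 0.28 and LOC100045782 fell by 0.49 (limma adjusted p 0.000953, 0.0101 and 0.00507). The authors' deposited tables share 14 probes, 7 higher in both and 7 lower in both, with 0 in opposite directions. Independent lists of these sizes would share 2.03 higher and 1.34 lower probes among all probes, with 1.45 and 1.87 in the opposite directions. Among probes with a mean log2 above 8 they would share 4.85 higher and 3.2 lower, with 3.47 and 4.47 opposite. These numbers take the tables as they are, and the TgMsi1 table leaves out probes past its own smallest fold. The shared rises were Tbx1, the pore-forming protein Gsdmd, the sodium pump subunit Fxyd2, Fez1, Fcer1g and 2 probes of Tnfrsf10b. The shared falls were Nckap1l, the guanine nucleotide exchange factor Rasgrf1, Pabpc2, Epsti1, Ehbp1, Prps1l3 and 4930430E16Rik. All 14 passed limma's threshold in TgMsi2, and 0 of them did in TgMsi1, where each had an unadjusted p under 0.05. Gsdmd was higher by 0.76 (SE 0.15) in TgMsi1 and rose by 1.10 (SE 0.15) in TgMsi2, and Rasgrf1 had values of -0.68 and -0.89 (SE 0.14 each). In the authors' deposited tables the ratio for Tbx1 was 1.73 in TgMsi1 and 1.76 in TgMsi2. Wt(TgMsi1) replicate 2 lay apart from the other wild-type arrays in Tbx1 (9.62), Fxyd2 (9.86) and Gsdmd (9.42), whose other Wt(TgMsi1) values were at most 8.79, 8.97 and 8.78.

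**Figure D2:**
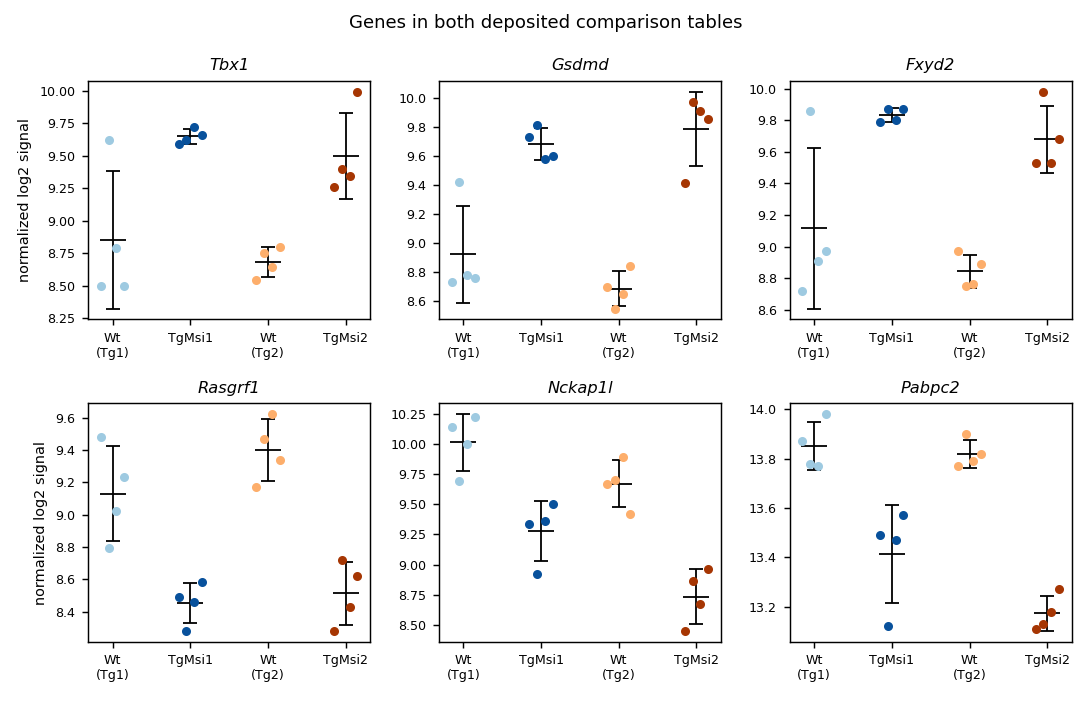
Normalized log2 signal (vertical axes) of 6 genes found in both deposited comparison tables, with 1 point per array, horizontal bars for group means and error bars for the SD of 4 arrays. Tbx1, Gsdmd and Fxyd2 lie higher and Rasgrf1, Nckap1l and Pabpc2 lower in TgMsi1 and TgMsi2 than in wild-type littermates, except that Wt(TgMsi1) replicate 2 reads 9.62, 9.42 and 9.86 in the first 3 genes.

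Across all probes, the fold changes of TgMsi1 and TgMsi2, which share no arrays, correlated with r = 0.539 (jackknife SE 0.207 over arrays), and probes are not independent replicates. Of the 2960 probes called in TgMsi2, 2472 (83.5%) had the same sign in TgMsi1. This share was not computed over all probes, in other splits of the arrays or without TgMsi1 replicate 2. It therefore does not show by itself that the transgenes share effects. The score of the 246 probes in the TgMsi1 table was 0.33 ± 0.07 in TgMsi2 testes and -0.12 ± 0.02 in their wild-type littermates (SD, n = 4 each), a difference of 0.46 in log2 units (exact permutation p = 0.0286, the smallest possible, higher in 4 of 4 arrays). In the other direction, the score of the TgMsi2-called probes was -0.10 ± 0.17 in TgMsi1 and -0.34 ± 0.06 in Wt(TgMsi1) (SD, n = 4 each), a difference of 0.24 that did not pass (exact permutation p = 0.0571). With probes taken from the deposited TgMsi2 table, as the first score took them from the TgMsi1 table, the difference was 0.43 (exact permutation p = 0.0571). The 2 directions are therefore not compared by size. This relation rested in part on TgMsi1 replicate 2. Without it r was 0.339, and the score difference was 0.16 for TgMsi2-called and 0.23 for TgMsi2-table probes (exact permutation p = 0.0857 each). Without TgMsi1 replicate 4 the score difference of TgMsi2-called probes was 0.29 (exact permutation p = 0.0286).

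**Figure D3:**
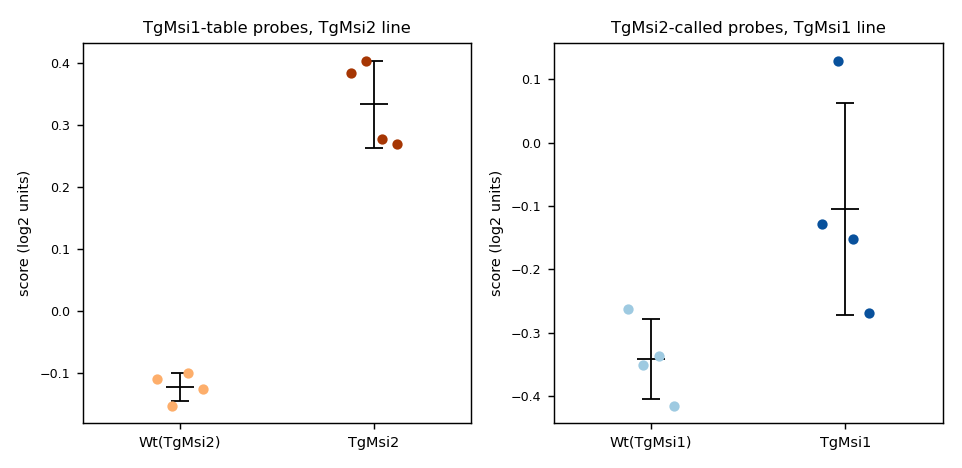
Score per array in log2 units (mean of a set's higher probes minus mean of its lower probes), with 1 point per array, group means and SD bars (n = 4), for TgMsi1-table probes in the TgMsi2 comparison and TgMsi2-called probes in the TgMsi1 comparison. Group means are 0.33 and -0.12 (transgenic and wild type) for the first and -0.10 and -0.34 for the second, where the groups overlap.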

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

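All tests of other array splits and of array positions in this part were chosen only after the results were seen. Single arrays stood apart from the 3 others of their group in 12 of 230 groups of 4 tested, where about 11.5 were expected by chance. Wt(TgMsi1) replicate 2 did so in 4 genes: Fez1 (10.38, others 9.93 to 9.98), Tnfrsf10b (9.49, others 9.01 to 9.08), Epsti1 (8.38, others 8.67 to 8.71) and Cnst (9.09, others 9.40 to 9.46), each time towards the TgMsi1 level. TgMsi1 replicate 2 stood high in Msmo1 (10.90, others 9.28 to 9.46) and in the prolactin receptor gene Prlr (10.51, others 9.82 to 9.89). The other single arrays were Wt(TgMsi1) replicate 3 in Fcer1g (8.35), Wt(TgMsi1) replicate 1 in Msmo1 (9.61), TgMsi1 replicate 4 in Ndufa4 (11.17), TgMsi2 replicate 1 in Serpina3g (12.12), Wt(TgMsi2) replicate 1 in Serpina3g (10.91) and Wt(TgMsi2) replicate 3 in Acta2 (10.92).

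Wt(TgMsi1) replicate 2 lay between the genotypes on probes that moved in both lines. Left out of the choice of probes, its median position was 0.53 on a scale from wild type (0) to transgenic (1), where the other wild-type arrays of the line lay at -0.17 to 0.19 and the TgMsi1 arrays at 0.54 to 1.21. Over probes with a mean log2 above 9 its position was 0.55, against -0.19 to 0.20 in the other wild-type arrays, which argues against noise of dim probes, and the TgMsi1 arrays lay at 0.49 to 1.17 there, so it lay above the lowest of them. Some other values lay on the wild-type side. Its score on TgMsi2-called probes was -0.35, against -0.27 to 0.13 in the TgMsi1 arrays. The first principal component of Wt(TgMsi1) replicate 2 was -12.1. Neither measure separated the genotypes fully, since TgMsi1 replicate 4 (-0.27 and -8.6) lay below Wt(TgMsi1) replicate 1 (-0.26 and -6.8). On the second principal component Wt(TgMsi1) replicate 2 lay at 14.9, near TgMsi1 replicates 2 and 4 (17.9 and 10.6). There TgMsi1 replicates 1 and 3 lay at -3.0 and -1.9, and the other wild-type arrays of the line at -10.2 to 3.0. Probes that moved in this line alone (0.81, with Wt(TgMsi1) replicate 3 at 0.70 and the TgMsi1 arrays at 0.49 to 0.66) did not separate the genotypes. A wrong label on this sample may explain the pattern (0.53), was not settled by these values and stays open. The transgene's own transcript was not read, and no biological explanation was tested.

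Grouping by chance was not excluded for the count of probes changed in TgMsi1: 4 of the 35 splits of the 8 arrays gave at least the 3 probes of the real split. The highest other split (TgMsi1 replicates 1 and 3 with Wt(TgMsi1) replicates 3 and 4, against the rest) gave 159, which points to a structure of these arrays other than genotype.

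The effects of the 2 transgenes differed by the interaction test for Tm9sf2 (-0.64) and ILMN_1377919 (0.44). Of 100 drawn splits, 4 (the real one included) gave at least as many probes as the real 2. This share lies just under the threshold of 0.05. The splits regroup arrays within each line, which removes the transgene effects too. They therefore do not test whether 2 equal effects would give as many calls. The count of 2 fell to 0 in 5 fits with 1 array left out (without TgMsi1 replicate 1 or 4 or Wt(TgMsi2) replicate 2, 3 or 4, with 2262 to 2624 probes at an unadjusted p under 0.05 in limma), so chance is not excluded. The highest other splits gave 531 and 6. Both kept all TgMsi2 arrays against all Wt(TgMsi2) arrays and regrouped only the TgMsi1 line, so their counts include the effect of TgMsi2 itself.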

How the results depend on the processing

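Fits over probes with a mean log2 above 8 and fits without named pairs of arrays were tests chosen after the data were seen. The TgMsi1 count (3) was 5 with array weights, 7 with an intensity trend and robust variance, 17 with the replicate number as a block, 0 from the line's own 8 arrays in limma (1791 at an unadjusted p under 0.05), 8 over probes with a mean log2 above 8, 9 without TgMsi2 replicates 1 and 3, 28 without replicate number 2 of both TgMsi1-line groups, 1 with a fold over 1.5 added, 26 with an unadjusted p and that fold, and 0 to 30 with 1 array left out. Of the 7 TgMsi1 calls with the trend, 1 was shared with the 3, and of the 17 with the block, 2 were. Ppa2 and Ano10 lost their calls with the trend, and Ano10 lost its call with the block. The TgMsi2 count (2960) was 201 without TgMsi2 replicates 1 and 3, 635 with the fold added, 706 with an unadjusted p and that fold, and 1305 to 3530 with 1 array left out. It was 3819 with array weights, 3103 with the trend, 3170 with the block, 2269 from its own 8 arrays and 3310 above a mean log2 of 8. The difference count (2) was 12 with the trend, 8 with the block (0 of them shared with the 2, so Tm9sf2 and ILMN_1377919 lost their calls, with 3139 probes at an unadjusted p under 0.05 in limma), 1 without TgMsi2 replicates 1 and 3, 47 without replicate number 2 of both TgMsi1-line groups, 1 with the fold added, 321 with an unadjusted p and that fold, and 0 to 107 with 1 array left out. The fold change correlation (0.539) was 0.309 without replicate number 2 of both TgMsi1-line groups and 0.339 to 0.596 with 1 array left out. With 1 array left out, the score difference of TgMsi2-called probes in the TgMsi1 line was 0.16 to 0.29 and that of TgMsi1-table probes in the TgMsi2 line 0.43 to 0.48. Of 48 named TgMsi2 genes that passed, 0 changed sign, 14 kept their call in all settings, and the number that lost it was 0 with array weights, 1 with the trend, 3 with the block, 6 from the own 8 arrays, 13 with any 1 array left out and 34 without TgMsi2 replicates 1 and 3. Msmo1 lost its call with the trend, and Acta2, Klk1b27 and Msmo1 lost theirs with the block. Aard, Acta2, Cyp11a1, Klk1b27, Msmo1 and Ndufa4 lost theirs in the fit of the own 8 arrays. Of 47 named TgMsi1 genes that did not pass, 11 passed in some setting and 10 changed sign in some setting. Whether replicate numbers pair the samples was not settled. Not every sample correlated best with its own number (r for the same number 0.02, 0.31, 0.45 and 0.19 in the TgMsi1 line, 0.37, 0.13, -0.32 and -0.01 in the TgMsi2 line), but noisy pairs could give this too. Other background corrections, median scaling, detection filters, the slide as a block and rank-based list tests were not run.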

Other observations

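The tests of gene ontology terms, array positions and array splits in this part were chosen only after the results were seen. Genes annotated to the mitochondrion were mostly higher in the authors' deposited TgMsi2 table: 34 higher and 5 lower (87.2% higher, against 64.3% of all annotated genes of the table; Fisher's exact test over 56 terms, adjusted p = 0.0421). Among them Acadm (0.76) and Echs1 (0.81) of fatty acid oxidation, the aminotransferase Got2 (0.63) and the adenine nucleotide carrier Slc25a5 (0.81) rose in limma. Genes annotated to the nucleus leaned to falls, with 35 higher and 43 lower (44.9% higher, adjusted p = 0.00972). Among the falls in limma were the homeobox gene Hoxa4 (-1.19), the zinc finger gene Zscan21 (-1.13 and -0.74 at its 2 probes), Rbl2 (-0.70) and the histone genes H3c1 (-0.95), H3c6 (-0.91) and H3c4 (-0.88). Cyp11a1 and Tspo, Leydig cell markers, are among the mitochondrial genes, and some somatic markers rose and at least 2 of 21 round spermatid markers fell in the same comparison, so these term results were not separated from a change of cell types. The histone genes are near-identical in sequence, and whether their probes tell them apart was not tested.

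Lysosomal genes (11 higher, 0 lower) such as Ctsb (1.29) and Lamp2 (0.95 at the probe that changed most), and lipid metabolism genes (15 higher, 1 lower) did not pass the adjustment (Fisher's exact test, adjusted p = 0.105 each), nor did spermatogenesis genes (3 higher, 7 lower, adjusted p = 0.189). X-linked genes of the deposited TgMsi2 table were 25 higher and 9 lower, against 283 and 204 on other chromosomes (Fisher's exact test, p = 0.103).

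The probes changed in TgMsi2 were weighed against a change carried by 1 or 2 transgenic arrays. Each array was left out and placed on the probes called without it. The lowest transgenic array (TgMsi2 replicate 4) lay at 0.53, with 54.0% of probes beyond the midpoint of the scale, and the highest wild-type array at 0.29. This argues against a change confined to 1 or 2 arrays, although replicates 1 and 3 lay furthest out (1.31 and 1.13). Without both TgMsi2 replicates 1 and 3, limma called 201 probes, and lost power was not separated from these arrays there. Of the 35 splits of the 8 arrays, 1 (the real one) gave as many as 2960 probes, and the highest other gave 2. This argues against grouping by chance, but 1 of 35 is the smallest share that 8 arrays allow, so chance is not firmly excluded. Litter and other differences between the mice were not tested.

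The rise of some Sertoli, Leydig and macrophage markers and the fall of at least 2 of 21 round spermatid markers in TgMsi2 could come from a lower share of germ cells in the tissue. The test assumed that such a loss raises markers of every somatic type alike. Endothelial markers were in the deposited TgMsi2 table as higher in 0 of 10 genes against 18 of 65 of the other somatic types (Fisher's exact test, p = 0.105). That table holds only folds of at least 1.5, so absence from it does not show that endothelial markers did not rise. Spermatogonia (20) and meiotic axis (22) markers had 0 members listed, and late spermatocyte (17) and elongating spermatid (22) markers had 1 each, lower. Robo4, a receptor of vascular endothelium outside that list, rose by 2.01 on the log2 scale, and the explanation stays open. The round spermatid count is a minimum over genes of the deposited TgMsi2 table, all with a fold of at least 1.5. It was therefore not ranked against shares of probes called at any fold. The marker lists are small and the table was selected on the same samples, so changed expression within each cell type and a changed share cannot be told apart.

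The correlation of the fold changes of TgMsi1 and TgMsi2 over probes with a mean log2 above 8 was 0.564. Of 100 drawn splits, 3 (the real one included) gave an absolute value as large, and the highest other gave 0.592. The value rests on TgMsi1 replicate 2, without which the correlation over these probes was 0.360 (0.330 without replicate number 2 of both TgMsi1-line groups). Of the 99 other splits of all arrays, 18 reached 0.360 in absolute value, and the splits were not repeated without that array, so chance is not firmly excluded.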
